A study of Caenorhabditis elegans with 2 samples.

How the data were processed

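The data are peak lists from chromatin immunoprecipitation sequencing of GFP-tagged DPL-1 in whole L4 larvae of C. elegans strain OP105, with 2 biological replicates of 1 group per the labels. Each replicate has a relaxed peak list and the series adds a relaxed list for the pooled replicates and an IDR-thresholded list, each on the builds ce11 and ce10. Per the deposited file listings, the relaxed list of a replicate was called on its alignment against a control alignment, the pooled list on both alignments, and the thresholded list was derived from the pooled and both replicate lists. The peak caller, the aligner and their versions are not given in the sources used here. The control reads and the signal tracks were not used here.

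The lists are in narrowPeak format per the deposited file listings. The signal of each peak is the authors' value, relative to the control alignment, and its scale is not given in the sources used here. It served to rank and filter peaks and, on the log10 scale, to compare bound genes within a list and the replicates at shared peaks, so the size of a ratio depends on that scale. The -log10 q of each peak is the authors' value too. It was equal for all 3369 IDR peaks (3.95) and therefore not used for ranking, and the p column holds a placeholder. The summit offset in bp from the peak start, also deposited by the authors, gave the summit position. Coordinates are 1-based on ce11. Each relaxed list holds exactly 30000 rows, which sets how weak a listed peak can be: the lowest signals were 6.37 in replicate 1, 4.19 in replicate 2 and 8.83 in the pooled list. The usual peak width was 370 bp in replicate 1, 250 bp in replicate 2 and 344 bp in the pooled list, so overlap of intervals depends on the list and summits were compared by distance. No read counts were used, so intervals cover the counting of genes and peaks only and not the depth of sequencing.

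Peak positions were matched to the WBcel235 genome, the same assembly as ce11, with the Ensembl release 115 annotation. All ce11 peak ends lay inside the chromosome lengths. A gene was called bound where an IDR summit lay from 500 bp upstream to 200 bp downstream of any annotated transcript start of a protein-coding gene on the 6 nuclear chromosomes (19973 genes). Many worm transcripts are trans-spliced or lie in operons, so an annotated start can lie downstream of where transcription begins. A summit in the windows of several genes counted for each.

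The comparisons, the 20 gene lists, the 6 motifs and the alternatives were fixed before the data were examined. Replicate agreement was the share of the strongest peaks of a replicate, as many as the IDR list holds, with a summit within 100 bp in the other, against 1000 random placements of summits within chromosomes. The promoter share was set against 1000 placements in the same way. Gene lists and the X chromosome were tested with Fisher's exact test, two-sided, and lists were adjusted by Benjamini-Hochberg over the 20 lists. Of the symbols in the lists, cdc-45, nuf-2, rad-54 and opt-2 matched no gene of the annotation and were left out. Signals of bound genes were compared by a two-sided permutation test of the difference in median log10 signal with 100000 resamples, for the 11 lists with 5 or more bound genes, adjusted over those. Motifs were compared between the window of 100 bp either side of the summit and a window centred 500 bp to one side, chosen at random with a fixed seed, by McNemar's exact test, adjusted over the 6 motifs. Intervals for shares are exact 95% Clopper-Pearson intervals. Transgene loci were described by percentiles among 10000 random windows. The ce10 lists were compared by rank only, with no conversion of coordinates.

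The rule for named genes was the gene with the nearest start for each of the 20 strongest IDR peaks, all members of the DRM and transgene lists, and the 3 bound members with the highest signal of each other list. For the chemoreceptor list, 1 of these members is not reported here. Not every gene that shares a summit with a named gene is named. Genes of the closing section outside this rule were chosen after their values were seen.

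The tests of gene lists, signal, promoter share, replicate agreement, motifs and spacing were run on simulated data, and the others were not. Of null lists of 60 genes among 19973, 4.50% had p under 0.05 in Fisher's exact test, and lists simulated with an odds ratio of 6.69 gave a median of 6.68. Null lists of 30 among 2700 bound genes passed the signal test in 5.25% of cases, and a doubled signal was found in 90.0% of lists. Genes were simulated as independent in both tests, so these rates do not cover genes that share a summit. Of 3000 planted summits 100% were assigned to their gene at the planted distance. A planted E2F site, present in 22.3% of 2000 windows, was counted in 22.7%, and no motif that had not been planted passed (lowest adjusted p = 0.63, McNemar's exact test).

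The alternatives were other summit distances (50 and 200 bp), overlap of intervals, other promoter windows (200 bp upstream to 100 bp downstream, and 1000 bp upstream to 200 bp downstream), assignment to the nearest start, the strongest 50% of the list, other backgrounds, other motif windows and controls, and the strongest peaks of a single replicate in place of the IDR list. Alternatives with random placement used 200 placements (100 for overlap of intervals), and those of the signal test 20000 resamples. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.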

Results

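The series asked where DPL-1 sits on the genome of the nematode Caenorhabditis elegans. DPL-1 is the worm DP protein, the partner through which E2F transcription factors bind DNA, and a member of the DRM complex, the worm counterpart of the DREAM complex that represses cell cycle genes. Chromatin immunoprecipitation with sequencing was run on whole L4 larvae of mixed sex from strain OP105, which carries an integrated transgene with dpl-1 fused to GFP. The labels give 1 group with 2 biological replicates and no second group, so no comparison between conditions could be made. The deposited peak lists hold 30000 relaxed peaks for replicate 1, 30000 for replicate 2, 30000 for the pooled replicates, and 3369 peaks that passed an irreproducible discovery rate (IDR) threshold, all on the ce11 build. The lists carry no read counts, so the depth of each library is unknown. Signal is the authors' value per peak, on a scale that is not given in the sources used here, and it is compared only within a list or between the replicates at shared peaks.

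The replicates placed their strongest peaks largely at the same positions. Of the 3369 strongest peaks of replicate 1, 2272 (67.4%) had a summit within 100 bp of one of the 3369 strongest summits of replicate 2. Random placement of the summits within their chromosomes gave 0.737% on average and 1.25% at most (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Random draws of as many peaks from the whole relaxed list of replicate 2 gave 9.16%. Of the 3369 IDR peaks, 3076 (91.3%) had a relaxed summit within 100 bp in both replicates and 10 had one in neither. At those 3076 peaks the signals of the replicates had a Spearman rho of 0.80 and a Pearson r of 0.85 on the log10 scale, across peaks, which are not independent replicates. The relaxed lists shared 84 summits at the same base, none with the same signal, so neither list is a copy of the other. The libraries were counted as separate biological replicates per the labels. The IDR list held exactly the 3369 pooled peaks with the highest signal, from 46.4 to 5205 with a median of 99.3.

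**Figure D1:**
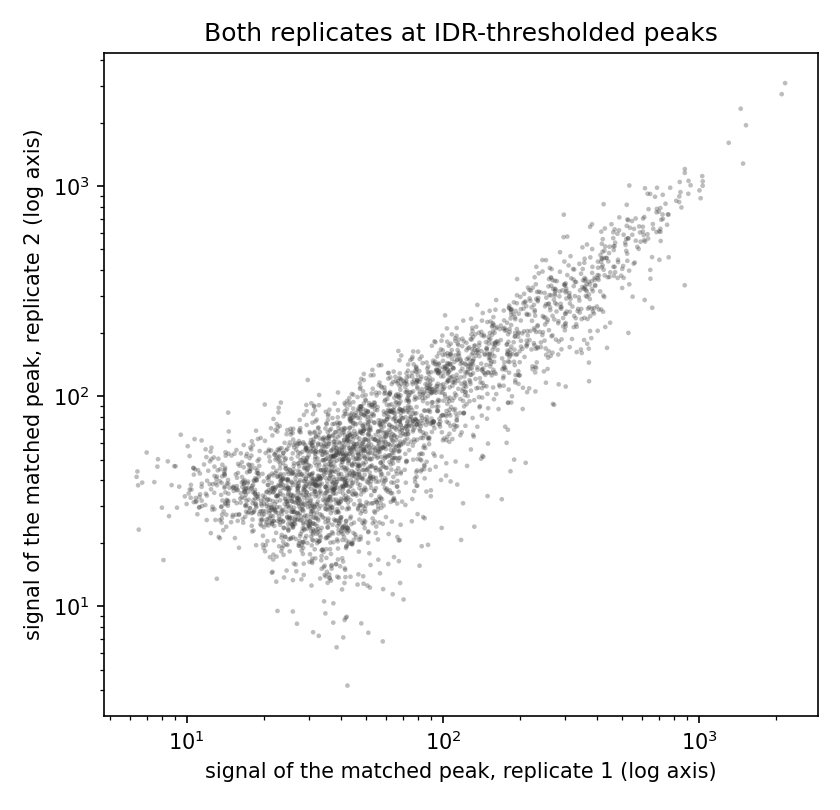
Each point is 1 of the 3076 IDR-thresholded peaks with a matched peak in both replicates, at its signal in replicate 1 (horizontal) and replicate 2 (vertical), on log axes in the authors' signal units. The points rise together, with a Spearman rho of 0.80 across peaks.

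DPL-1 peaks lay mostly just upstream of protein-coding genes. Of 3369 IDR summits, 2124 (63.0%) fell in a promoter window, from 500 bp upstream to 200 bp downstream of an annotated protein-coding transcript start. Coding sequence outside those windows held 9 summits (0.267%), against 20.6% of random positions, introns held 392 (11.6%) against 30.7%, and intergenic sequence held 721 (21.4%), less than at random positions. The median summit lay at -177 bp from the nearest start, and 82.0% of summits lay on the upstream side. Random placement put 16.4% ± 0.633 (SD over placements) of summits in the windows and never more than 18.3% (one-sided permutation p = 0.001, the smallest that 1000 placements can give). In all, 2701 of 19973 protein-coding genes (13.5%) had an IDR summit in their window. These genes are called bound below, and 636 of the 2124 window summits counted for more than 1 gene. Of the 63 genes named by the rule in the methods that have a summit in their window, 26 share it with another gene, not always named here, so a peak need not belong to the named gene alone.

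The 20 strongest peaks lay near genes of several kinds, among them a gene of the E2F family itself. The highest signal in the IDR list, 5205, was at III:3867301-3867800, with its summit at -283 bp from the start of rpl-3, which encodes a large-subunit ribosomal protein, and this peak ranked 2 in replicate 1 and 1 in replicate 2. The next, with a signal of 4800, was at II:10563358-10563795, with its summit at -168 bp from the start of cdc-48.1, which encodes an AAA ATPase that unfolds ubiquitinated proteins. The third stood at rpl-35, another ribosomal protein gene, with 3799. Peaks at tasp-1 (3495), cox-5A (2914), which encodes a cytochrome c oxidase subunit, citk-2 (2736), sec-61.G (2129), a subunit of the protein translocon, and eif-3.C (2122), a subunit of the translation initiation factor eIF3, followed. The rest of the 20 strongest had as their nearest gene eelo-2, the chaperone gene dnj-9, the lipoamide dehydrogenase gene dld-1, F48A11.4, efl-1, the alpha-tubulin gene tba-2, nlp-40, ddp-1, fbxl-2, T23F6.3, vig-1 and the mitochondrial import gene tomm-20, with signals from 2082 at eelo-2 down to 1720 at tomm-20. Of these 20 peaks, the one assigned to nlp-40 was the exception in position: it was intergenic, with its summit 1918 bp downstream of the start of nlp-40 and outside every promoter window.

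Genes of the DRM complex were themselves bound. Of the 8 members, 5 had an IDR summit in their window (62.5%, exact 95% interval 24.5 to 91.5%), against 13.5% of all other genes (odds ratio 10.7, interval 2.08 to 68.8, Fisher's exact test, adjusted p = 0.0050). The peak of efl-1, which encodes the E2F partner of DPL-1, had a signal of 1946 and ranked 13 among all IDR peaks, 12 in replicate 1 and 19 in replicate 2. Its summit lay at V:16965850, at -175 bp from the annotated start. The DNA-binding subunit gene lin-54 had a peak of 1272, lin-9 one of 1030, the histone chaperone gene lin-53 one of 970 and lin-35, which encodes the worm retinoblastoma-family protein, one of 581. The windows of lin-54, lin-53 and lin-35 share their summits with rpl-12, nra-2 and vps-51. At lin-37 and lin-52 the pooled relaxed list held weak summits of 12.4 and 10.8, below the IDR minimum of 46.4. The window of dpl-1 held no summit in any list, and the stretch around it is described below. With genes that have another start within 1 kb left out, 2 of 4 DRM genes were bound and the adjusted p was 0.086 (Fisher's exact test). Against a background of genes with a relaxed pooled summit it was 0.21 (Fisher's exact test).

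Genes of DNA replication and mitosis carried DPL-1 peaks at several times the genome's rate. Of 43 replication genes, 35 were bound (81.4%, exact 95% interval 66.6 to 91.6%, odds ratio 28.3, Fisher's exact test, adjusted p = 7.6e-23). Among them pcn-1, the sliding clamp PCNA, had a signal of 1632, followed by tim-1, the worm Timeless gene, with 1078 and the replisome gene ctf-4 with 1076. The summits of tim-1 and ctf-4 also counted for Y75B8A.23 and eef-1G. Of 57 genes of mitosis, 44 were bound (77.2%, interval 64.2 to 87.3%, odds ratio 22, Fisher's exact test, adjusted p = 1.1e-26). The strongest of these were top-2 (1478), which encodes topoisomerase II and shares its summit with the nucleoporin gene npp-3, the kinetochore gene knl-3 (1209) and the condensin gene hcp-6 (963). Those of knl-3 and hcp-6 are shared with T10B5.3 and let-630. DNA repair and checkpoint genes were bound in 24 of 46 cases (52.2%, interval 36.9 to 67.1%, odds ratio 7.03, Fisher's exact test, adjusted p = 1.6e-09). Their strongest peaks were at the translesion polymerase gene polh-1 (1212), whose summit also counted for rps-22, and at the checkpoint genes hpr-17 (1197) and mrt-2 (1063). F32A11.1 shares the hpr-17 summit. Taken from the strongest peaks of a single replicate, the counts of bound replication genes (35 and 35) and mitosis genes (44 and 44) did not move. Of 11 centrosome genes 5 were bound (odds ratio 5.34, Fisher's exact test, adjusted p = 0.023), led by the centriole genes sas-5 (632) and sas-6 (431) and by spd-2 (260). Y45F10D.7 and F32H2.10 share the summits of sas-6 and spd-2. The centrosome call was lost with genes that have a start within 1 kb of another left out (adjusted p = 0.38, Fisher's exact test) and against genes with a relaxed summit (adjusted p = 0.46, Fisher's exact test).

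Many ribosomal protein and proteasome genes, which are not cell cycle genes, were bound too. Of 78 cytosolic ribosomal protein genes, 69 were bound (88.5%, exact 95% interval 79.2 to 94.6%, odds ratio 50.3, Fisher's exact test, adjusted p = 2.7e-49), with rpl-3, rpl-35 and rps-12 (1550) the strongest. The rps-12 summit also counted for ska-3. Of 33 proteasome genes, 27 were bound (81.8%, interval 64.5 to 93%, odds ratio 29.0, Fisher's exact test, adjusted p = 6.0e-18). They were led by rpn-11 (997), the deubiquitinating subunit of the lid, and by the core subunit genes pas-5 (648) and pbs-1 (614). K08D12.3 shares the pbs-1 summit. The median ribosomal summit lay at -293 bp from the annotated start (quartiles -365 and -254, 69 genes), and at 60 of the 69 genes it lay over 200 bp upstream. The median was -153 bp for replication genes, -161 bp for mitosis genes, -185 bp for proteasome genes, -245 bp for the 5 bound chemoreceptor genes and -173 bp for all bound genes, and these distances were not tested against each other. In a window from 200 bp upstream to 100 bp downstream only 9 of 78 ribosomal protein genes were bound, and the difference from other genes no longer passed the test (odds ratio 1.59, Fisher's exact test, adjusted p = 0.28).

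Several lists tied to the cell cycle or to chromatin did not pass the test against other genes. Of 20 E2F and G1/S genes, 6 were bound (30%, odds ratio 2.74, Fisher's exact test, adjusted p = 0.073), with efl-1, lin-35 and the ubiquitin ligase gene cul-4 (232) the strongest. The cul-4 peak had a relaxed summit within 100 bp in replicate 2 only. The E2F and G1/S list passed in the window reaching 1000 bp upstream (adjusted p = 0.017, Fisher's exact test) and with the nearest start only (adjusted p = 0.033, Fisher's exact test). Of 8 other synMuv B genes, which antagonise vulval induction, 2 were bound: lin-36 (436) and lin-61 (207), which shares its summit with the checkpoint kinase gene bub-1. The adjusted p was 0.42 (Fisher's exact test), and 0.044 in the window reaching 1000 bp upstream, where 4 of the 8 were bound. Meiosis genes were bound in 4 of 28 cases (adjusted p = 0.91, Fisher's exact test), led by the recombinase gene rad-51 (289), with syp-3 at 78.2 and him-17 at 62.6. Germline and P granule genes were bound in 6 of 40 cases (adjusted p = 0.91, Fisher's exact test), with mes-2 (976) and mes-6 (314), of the worm Polycomb complex, and the chromodomain gene mrg-1 (427) the strongest. Of 10 cell death genes, cep-1 alone, the worm p53 gene, was bound (95.3, adjusted p = 1.0, Fisher's exact test). Histone genes were bound in 15 of 72 cases (adjusted p = 0.13, Fisher's exact test) through 9 summits, with his-37 (732) far above the pair his-67 and his-68 (167, a shared summit). Histone genes passed in the window from 200 bp upstream to 100 bp downstream (odds ratio 2.95, adjusted p = 0.0027, Fisher's exact test) and among genes with a relaxed summit (odds ratio 8.23, adjusted p = 0.00033, Fisher's exact test). The number of bound histone genes was 6 when replicate 2 was left out and 15 when replicate 1 was.

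Genes of differentiated tissues were bound no more than other genes, and some lists less. Of 1293 chemoreceptor genes, which neurons express, 5 were bound (0.387%, exact 95% interval 0.126 to 0.900%, odds ratio 0.0230, Fisher's exact test, adjusted p = 3.5e-74). Sperm genes were bound in 2 of 74 cases (2.70%, odds ratio 0.177, Fisher's exact test, adjusted p = 0.0080), namely spe-39 (680), which shares its summit with spn-4, and spe-48 (189). The sperm call was lost in 5 alternatives, with adjusted p from 0.065 (nearest start only) to 0.63 (genes with a relaxed summit) (Fisher's exact test). None of 33 cuticle and epidermal genes was bound (adjusted p = 0.036, Fisher's exact test), and none of 29 intestinal genes (adjusted p = 0.048, Fisher's exact test). The cuticle and intestine calls were narrow: without replicate 2 their adjusted p were 0.21 and 0.053, and without replicate 1 they were 0.035 and 0.56 (Fisher's exact test). Muscle genes were bound in 3 of 32 cases (adjusted p = 0.91, Fisher's exact test), with unc-112 (99.3), pat-6 (56.4) and unc-60 (53.1), all attachment or actin genes of the body wall. The unc-60 peak had a relaxed summit within 100 bp in replicate 2 only. Neuronal genes were bound in 3 of 37 cases (adjusted p = 0.63, Fisher's exact test), with the synaptobrevin gene snb-1 at 84.7, ric-3 at 52.8 and egl-21 at 49.1. In all, 7 of 20 lists held more bound genes than the rest of the genome and 4 held fewer. Genes that share a promoter are not independent, but the tests count each gene as if it were.

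**Figure D2:**
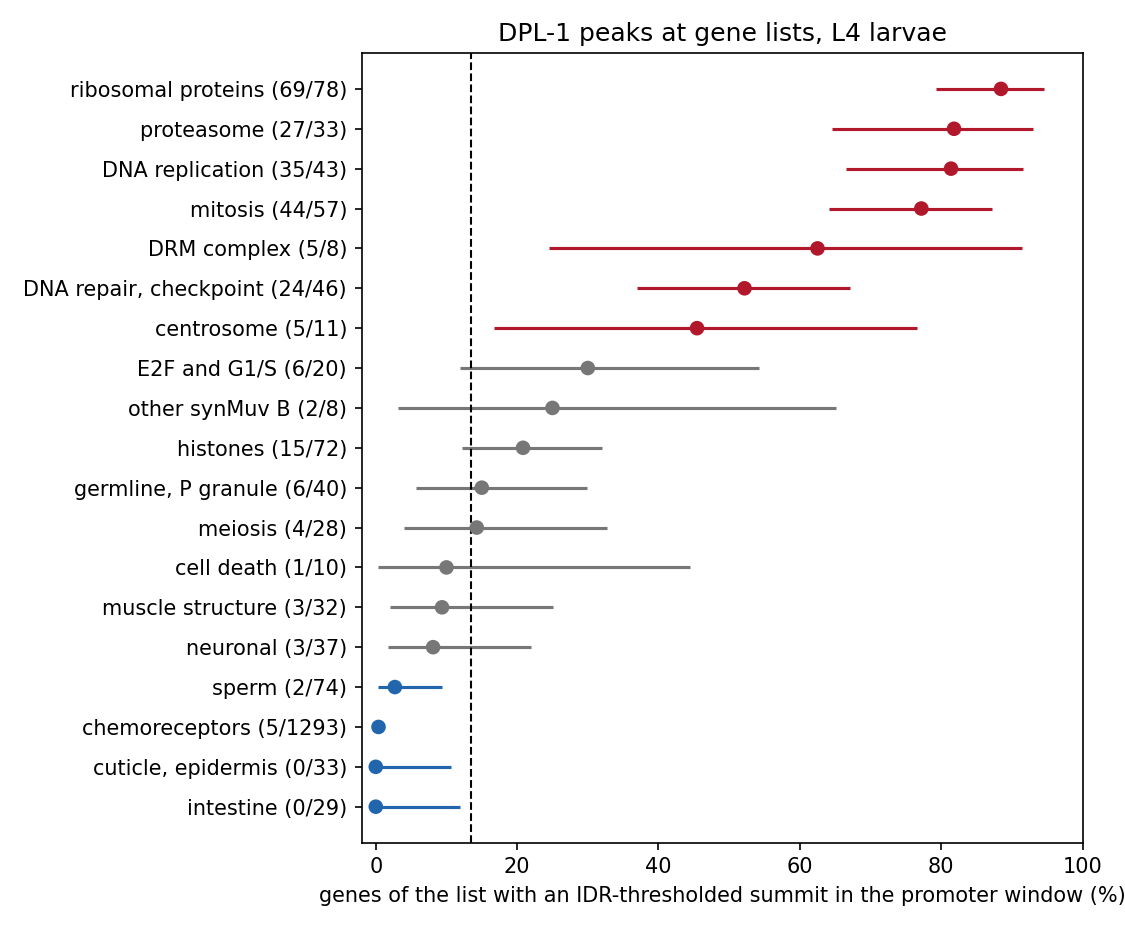
Share of each gene list with an IDR-thresholded summit in the promoter window (points, %) with exact 95% binomial intervals (lines); the dashed line is the share of all genes, 13.5%. Red lists passed the test with more bound genes and blue lists with fewer, and ribosomal proteins (69 of 78) and chemoreceptors (5 of 1293) are the extremes among the lists with any bound gene.

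Among bound genes, those of the DRM complex, replication, mitosis, repair and the ribosome had stronger peaks than the rest. The median signal was 1030 at the 5 bound DRM genes against 147 at all other bound genes, a ratio of 7.0 (two-sided permutation test, adjusted p = 0.0026). The ratio was 2.54 for 35 replication genes (permutation test, adjusted p = 0.00038), 1.97 for 69 ribosomal protein genes (permutation test, adjusted p = 0.00033), 2.02 for 24 repair genes (permutation test, adjusted p = 0.013) and 1.78 for 44 mitosis genes (permutation test, adjusted p = 0.0079). With the signal of replicate 2 alone, the repair and mitosis lists had ratios of 1.76 and 1.53, and neither passed (adjusted p = 0.058 for both, permutation test). The 27 bound proteasome genes, with a median of 158, did not differ (ratio 1.08, permutation test, adjusted p = 0.78). The 5 bound chemoreceptor genes had a ratio of 3.65 (permutation test, adjusted p = 0.036, and 0.16 without replicate 1). Among them, sri-5 (1158) shared its summit with rsr-1 and srd-4 (540) with usip-1, which belong to other families. Bound histone genes had a ratio of 0.569 (permutation test, adjusted p = 0.13), which without replicate 2 was 0.326 (adjusted p = 0.0049, permutation test). E2F and G1/S genes (1.27), centrosome genes (1.76) and germline genes (1.92) did not pass (adjusted p = 0.67, 0.35 and 0.21, permutation test).

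The sequence elements known for E2F and for LIN-54 were more frequent at the strongest peaks than at the weakest, and a GAGAG repeat was over-represented at both. Over all 3369 summits, the E2F site TTSSCGC (S is C or G) was found within 100 bp in 670 windows (19.9%), against 232 (6.89%) of control windows 500 bp away, with 3.34 windows that had it at the summit alone for each that had it in the control alone (McNemar's exact test, adjusted p = 2.1e-55). The reversed sequence, which has the same base composition, gave a ratio of 3.71 (12.2% against 3.56%, McNemar's exact test, adjusted p = 6.6e-40), so the composition control was over-represented too. The ratios of the site and its control were not tested against each other, and without replicate 2 they were 3.59 and 2.81. The CHR element TTYGAA (Y is C or T), which LIN-54 binds, was in 48.8% of summit windows and 51.6% of controls (ratio 0.898, McNemar's exact test, adjusted p = 0.028). This call was not stable: without replicate 2 the ratio was 1.11 (McNemar's exact test, adjusted p = 0.033). It did not pass with 200 bp either side or with the control at 1000 bp. Its control TTRGAA (R is A or G) was in 23.3% and 37.1% (ratio 0.513, adjusted p = 1.2e-34, McNemar's exact test), and the TATA box TATAAA in 14.2% and 20.2% (ratio 0.660, adjusted p = 1.8e-10, McNemar's exact test). The repeat GAGAG was in 54.1% against 24.9% (ratio 3.51, McNemar's exact test, adjusted p = 2.4e-127).

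The list average hid a gradient with peak signal, which was examined after the data were seen. In the strongest 10% of the list, 269 of 336 windows (80.1%) held the CHR element, against 146 of 337 (43.3%) in the weakest 10% (odds ratio 5.24, Fisher's exact test, adjusted p = 2.5e-22). The E2F site was in 39.3% and 11% (odds ratio 5.23, Fisher's exact test, adjusted p = 2.1e-17), and its reversed control in 20.8% and 9.79% (odds ratio 2.42, Fisher's exact test, adjusted p = 0.00010). The CHR control did not differ between the strongest and the weakest peaks (23.2% and 24.3%, Fisher's exact test, adjusted p = 0.79). GAGAG went the other way, from 39.9% to 62.6% (odds ratio 0.397, Fisher's exact test, adjusted p = 8.2e-09). Within the strongest 10%, CHR stood out against the control windows with a ratio of 5.50 and E2F with 12.5 (McNemar's exact test, adjusted p = 2.7e-20 and 1.2e-25). The reversed E2F motif (ratio 4.6, adjusted p = 3.9e-09) and GAGAG (ratio 2.36, adjusted p = 5.7e-07) stood out there too (McNemar's exact test). In the strongest 50% the CHR ratio was 1.40, with the opposite direction to the whole list (McNemar's exact test, adjusted p = 1.9e-06).

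**Figure D3:**
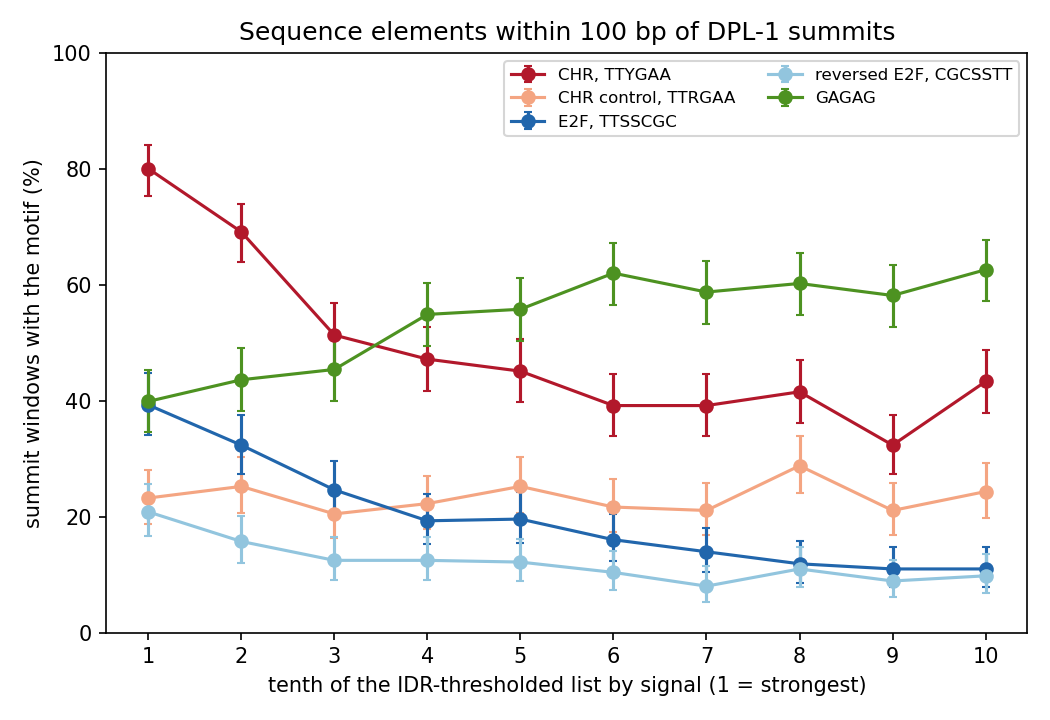
Share of summit windows (100 bp either side, %) with each sequence element, for 10 equal parts of the IDR-thresholded list from the strongest (1) to the weakest (10), with exact 95% binomial intervals. CHR goes from 80.1% in the strongest part to 43.3% in the weakest and E2F from 39.3% to 11%, while GAGAG goes from 39.9% to 62.6%.

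The X chromosome held fewer DPL-1 peaks than the autosomes. Of 2731 X-linked protein-coding genes 207 were bound (7.58%), against 2494 of 17242 autosomal genes (14.5%, odds ratio 0.485, interval 0.416 to 0.563, Fisher's exact test, p = 2.7e-25). Per Mb the X held 22.1 IDR summits and the autosomes 36.1. The autosomes differed among themselves: chromosome III had 50.4 summits per Mb and 22.1% of genes bound, chromosome I 47.1 and 21.2%, chromosome II 36.3 and 13.2%, and chromosome IV 30.5 and 12.8%. Chromosome V, where many chemoreceptor genes lie, had 23.2 summits per Mb and 8.49% of genes bound, which is close to the X. The median signal of X peaks was 77.9, the lowest of the 6 chromosomes. In the strongest 50% of the list the odds ratio for the X was 0.309 (Fisher's exact test, p = 1.0e-35).

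**Figure D4:**
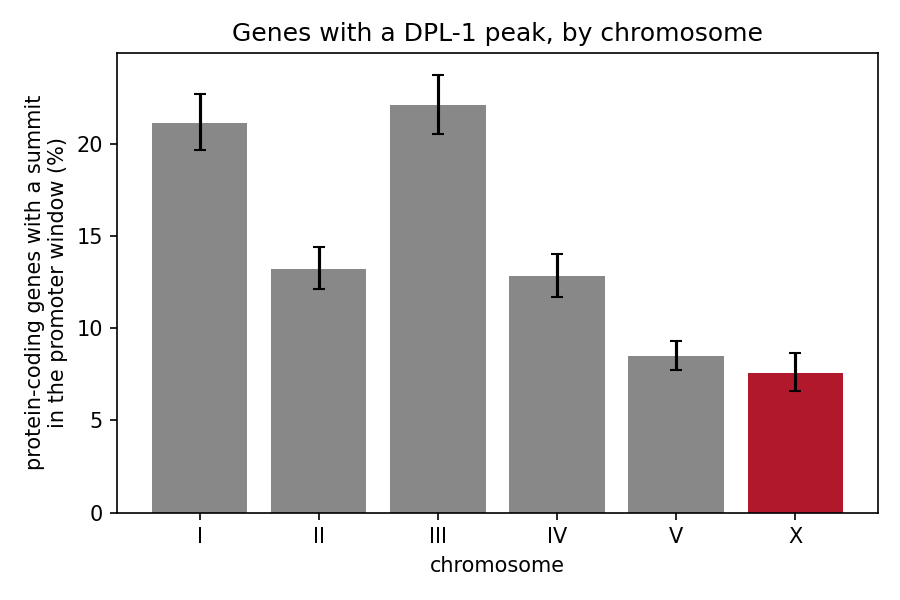
Share of the protein-coding genes of each chromosome with an IDR-thresholded summit in the promoter window (bars, %) with exact 95% binomial intervals. The X (red) has 7.58% and chromosome III 22.1%.

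The transgene loci differed from each other. The strain carries extra copies of dpl-1 and of the rescue gene unc-119. No summit of the pooled or of either replicate's relaxed list lay within 20 kb of dpl-1 (II:9169910-9172565), where random windows of that size held a median of 11 in each list. The nearest pooled summits lay at II:9145965 and II:9196453, 50.5 kb apart, with 12 protein-coding genes between them. Around unc-119 (III:10902641-10908935) the pooled list held 12 summits, at percentile 50.3 of 10000 random windows, and each replicate's list held 15. The lists on ce10 were compared with those on ce11 by rank only. The ce10 IDR list held 3438 peaks, 69 more than on ce11, with a lowest signal of 45.5 in place of 46.4, and peaks of the same rank differed in signal by at most 1.11% between the builds (1.29% in the relaxed list of replicate 2).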

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

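The test of gene loci in long gaps and that of the gap edges at dpl-1, the test of the CHR control motif, the test of the gradient among peaks in both replicates and the comparison of the strongest and weakest 10% were chosen after their results were seen.

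On the mitochondrial genome, which no comparison of genes, promoters or motifs used, replicate 1 had its strongest peak of all (M:12838-13387, signal 4325) and a second one (M:13577-13794, signal 291, rank 275), while the lists of replicate 2 and of the pooled replicates held none there. Both peaks were among the strongest of replicate 1 in the test of replicate agreement.

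The absence of summits around dpl-1 stands out because the strain carries extra copies of that gene. In the test set beforehand, 2.53% (exact 95% interval 2.23 to 2.86%) of 10000 random autosomal intervals of 50.5 kb with a number of genes within 2 of the 12 there held no pooled summit, under its bound of 5%, but that bound was wrong because the interval was drawn from summit to summit and so was empty and of maximal length by construction. Of 7359 other autosomal genes with a number of genes around them within 2 of the 12 around dpl-1, 7.26% (95% interval 4.59 to 10.2% over blocks of 1 Mb) lay in a pooled gap at least as long, so chance stays open. The interval was not poor in genes, with 12 in 50.5 kb against 3449 in the 15.3 Mb of chromosome II. That argues against few genes as the source. The gap ranked 87 by length among 29994 in the pooled list (41 in replicate 1, 70 in replicate 2). Its edges, the nearest summits, differed by at most 1252 bp between the replicates, as close as at 2 of the 200 other longest pooled gaps (median 19027 bp). Those 200 gaps were chosen by the pooled list alone, while the stretch at dpl-1 was known to hold no summit of either replicate within 20 kb. Close edges were thus partly built into that choice, and the comparison cannot decide for a cause. Extra copies of the tagged dpl-1 clone, or a filter set on them, may leave such an interval, but peak lists cannot separate these from each other, and with 1 strain no biological explanation was tested.

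The replicates differed on the piRNA clusters of chromosome IV. In 97 windows of 50 kb with at least 50 piRNA genes each, the relaxed list of replicate 1 held 1360 summits and that of replicate 2 held 503, against 28576 and 29435 in all other windows (odds ratio 2.79, interval 2.51 to 3.10, Fisher's exact test, p = 9.6e-94, with summits taken as independent). The median log2 ratio was 1.66 (interval 1.38 to 2.00) in the clusters and 0.88 (0.69 to 0.89) in windows elsewhere matched on GC content. The low GC content of the clusters could thus account for part of the excess, and what sets the clusters apart beyond it stays open. The 291 matched windows could repeat and still held 479 piRNA genes. Windows were resampled as independent, so these intervals may be too narrow. Among the strongest peaks, as many as the IDR list holds, the clusters held 85 of replicate 1 and 78 of replicate 2 (odds ratio 1.09, interval 0.790 to 1.51), so the excess may be one of weak background summits. Both replicates belong to the same group, so no biological explanation was tested.

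The loss of the E2F and CHR elements from strong to weak peaks was weighed against artefacts. From the strongest to the weakest 10% of the list, the share of CHR fell by 36.7 percentage points. The CHR control was lower by 1.12 points in the strongest (a difference of -1.12), which argues against base composition as the only source for CHR. Against the control windows the CHR control did move the same way, with ratios of 0.720 in the strongest and 0.509 in the weakest 10%. Those of CHR were 5.50 and 0.740. For E2F the reversed control moved too, by 11 points against 28.3, so composition may carry part of the E2F gradient. Against the control windows the reversed motif moved little, with ratios of 4.6 in the strongest and 4 in the weakest 10%. Those of E2F were 12.5 and 1.46. Among peaks with a relaxed summit in both replicates, which 77.7% of the weakest 10% had, the odds ratios between the strongest and weakest 10% were 5.44 for CHR (interval 3.74 to 7.99) and 4.99 for E2F (3.18 to 8.03, Fisher's exact test). All 336 of the strongest and 262 of the 337 weakest peaks were kept, and removing so few could not have ended the difference. The odds ratios therefore show only that the gradient is present among peaks with a relaxed summit in both replicates. Relaxed signals go down to 6.37 in replicate 1 and 4.19 in replicate 2. The test therefore cannot exclude peaks that are strong in 1 library and weak in the other. With 1 group, no biological explanation was tested.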

How the results depend on the processing

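No paired analysis was possible because the study has a single group. Of 272 tested comparisons with an alternative, 230 kept their side of the threshold, and their direction too where the results passed. Another 33 comparisons were of counts with no test, and 27 of them stayed within 1.5 times the main count. The strongest and weakest 10% of the list, the limit to summits in both replicates, and the single-replicate values of the transgene loci were chosen after seeing the data. Unless stated otherwise the cause of a change was not tested. Replicate agreement ranged from 23.1% with the whole relaxed lists to 80.2% with the strongest 50%, and the promoter share from 39.2% in the narrow window to 78.2% in the strongest 50%, all above every random placement. The odds ratio of the X ranged from 0.309 to 0.541. The lists of replication, mitosis, repair, proteasome and chemoreceptor genes kept their calls in the test of bound genes under every alternative run. The lack of read counts limits all values: no weak peak can be called absent.

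Lists with fewer bound genes numbered 4, and 1 each in the narrow window, with the nearest start, in the strongest 50% and among genes with no other start within 1 kb. Fewer genes are bound in these 4 settings (1118 to 2073, against 2701). They numbered 2 without replicate 2 and 3 without replicate 1. In each of those first 4 settings the odds ratio was 0 for intestine and 0 for cuticle genes with neither passing, as it was for intestine with summits in both replicates (0). Without a replicate the odds ratio lay between 0 and 0.483 for intestine and between 0 and 0.207 for cuticle genes. Sperm genes no longer passed at 0.336 (narrow window), 0.239 (nearest start), 0.282 (strongest 50%), 0 (no other start) and 0.468 (genes with a relaxed summit).

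In the narrow window ribosomal protein genes did not pass (1.59), since the summits of 60 of their 69 bound genes lie further upstream, and histone genes passed (2.95), as they did among genes with a relaxed summit (8.23). E2F and G1/S genes passed at 3.42 with 1000 bp upstream and at 3.71 with the nearest start, and other synMuv B genes at 5.12 with 1000 bp upstream. DRM genes did not pass at 12.3 and centrosome genes at 4.11 among genes with no other start, where 4 of each list remain, nor at 4.10 and 2.05 among genes with a relaxed summit.

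Lists with stronger peaks numbered 6, and 3 to 6 with a single replicate's signal. The range of the ratio was 1.53 to 1.80 for mitosis, 1.76 to 2.21 for repair, 2.38 to 4.98 for chemoreceptor and 0.326 to 0.726 for histone genes.

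The CHR ratio, 0.898 over the list, turned to 1.40 in the strongest 50%, 5.50 in the strongest 10% and 1.11 without replicate 2 (0.819 without replicate 1). It no longer passed at 0.898 with 200 bp either side, 0.926 with the control at 1000 bp and 0.740 in the weakest 10%. TATA turned to 1.03 with 200 bp either side and did not pass at 0.871 in the strongest 50% and 0.940 in the strongest 10%. The CHR control did not pass at 0.720 in the strongest 10%, nor E2F at 1.46 in the weakest 10%.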

Other observations

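The spacing test below by shuffled pairs, with its controls, was chosen after the counts were seen, and the gene families, the 8-base sequences, the non-coding classes and the motifs at lists were examined after the main comparisons.

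Genes were also grouped by the family part of their symbol, which overlaps the lists fixed in advance. Of 175 families with 10 or more members, 24 had more bound genes than the rest of the genome and 37 had fewer (Fisher's exact test, Benjamini-Hochberg over the 175). All members of 3 of the 24 and of 16 of the 37 belong to the fixed lists. Translation initiation factors (eif) were bound in 19 of 25 cases, led by eif-3.C (2122) and eif-3.B (1172) (adjusted p = 1.0e-10, Fisher's exact test). Nucleoporins (npp), the proteins of the nuclear pore, were bound in 19 of 26 cases, led by npp-3 (1478) and npp-19 (1309) (adjusted p = 2.6e-10, Fisher's exact test). Subunits of RNA polymerase II (rpb) and of the Integrator complex (ints) were bound in 9 of 11 cases each (adjusted p = 7.9e-06 for both, Fisher's exact test), with the strongest peaks at rpb-11 (1689) and ints-4 (1225). Mitochondrial ribosomal proteins were bound in 17 of 29 (mrps) and 18 of 41 (mrpl) cases. Cyclin-dependent kinases (cdk), 3 of them in the fixed lists, were bound in 9 of 11 cases, led by cdk-5 (353) and cdk-1 (278). C-type lectins (clec) were bound in 4 of 240 cases (adjusted p = 3.2e-09, Fisher's exact test) and nuclear hormone receptors (nhr) in 13 of 269 (adjusted p = 3.6e-05, Fisher's exact test).

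The elements at the peaks of each bound list were compared with those at the other promoter peaks. The E2F site was at 27 of 35 peaks of replication genes (77.1%) and 25 of 44 of mitosis genes (56.8%), against 20.9% and 21.1% of the other promoter peaks (adjusted p = 1.0e-10 and 6.1e-06, Fisher's exact test over 33 comparisons). CHR was at 82.9% of replication, 88.6% of mitosis and 91.7% of repair peaks (adjusted p = 0.0059, 4.0e-05 and 0.0019, Fisher's exact test), against 55% of the others. Ribosomal protein peaks had E2F in 7 of 66 cases (10.6%) and CHR in 33 of 66, and did not pass against other promoter peaks (adjusted p = 0.11 and 0.54, Fisher's exact test). No list was tested against another. A single peak can count for a gene of each kind.

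Several classes of non-coding genes lay close to peaks. Of 612 tRNA genes, 159 (26%) had an IDR summit within 200 bp, against 1.43% on average and 3.27% at most in 1000 random placements (permutation p = 0.001, the smallest possible). The shares were 22.3% of 346 snoRNA genes and 16.3% of 129 snRNA genes (permutation p = 0.001 for each, the smallest possible). Placement was not limited to gene-rich or open sequence. Of 15363 piRNA genes, 38 (0.247%) had one, against 1.28% at random.

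The most over-represented 8-base sequence at IDR summits was AGACGCAG (CTGCGTCT on the other strand), in 520 of 3369 summit windows (15.4%) and 44 control windows (1.31%) (McNemar's exact test, Bonferroni p = 1.5e-105 over 32715 sequences). It was in 18.1% of the weakest 10% of peaks. In the strongest 10% the leading sequences were AAACGCGC, in 37 windows and no control (Bonferroni p = 2.9e-07, McNemar's exact test), and CGCGCAAA. Neither holds the full E2F site TTSSCGC on either strand. The next, AATTCAAA, holds a CHR element and was in 25.9% of windows against 7.44% of controls (Bonferroni p = 3.3e-06, McNemar's exact test).

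A hypothesis that E2F and CHR elements sit at a fixed spacing in the strongest peaks was tested. Of 132 peaks with an E2F site among the strongest 10%, 15 had a CHR element on the same strand with its centre 6.5 bp upstream (a spacing of -6.5 bp), directly next to it. This was 22.1 times the mean of the other spacings, but the reversed motif gave 25.7 by that measure, which therefore decided nothing. Shuffles that paired sites of different peaks gave at most 7 at any one spacing (permutation p = 0.0010, the smallest that 1000 shuffles can give). The reversed E2F motif also exceeded its shuffles, with 7 against at most 5 (permutation p = 0.001, the smallest possible), at -10.5 bp. Of these 7, 2 overlapped an E2F site, and reversed sites with no such overlap still gave 5 at that spacing, against at most 4 in shuffles (permutation p = 0.001, the smallest possible). Hence the test does not single out the E2F site, and a spacing rule cannot be told apart from base composition or another shared sequence.

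The longest stretch with no pooled relaxed summit was V:2319150-2577253 (258 kb), with 62 protein-coding genes. In it 84.0% of 36-base words occurred more than once, against a median of 1.03% and at most 7.61% in 20 random intervals of that length. Inside the unc-119 gene, 6.30 kb long, replicate 2 had 7 summits (percentile 97.6 of random windows), replicate 1 had 4 (82.8) and the pooled list 5 (89.2).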
